A study of Danio rerio with 6 samples.

How the data were processed

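The deposited matrices held raw UMI counts per gene and barcode for 6 libraries, as the authors deposited them and per the file headers, which mark them as integer matrices. Each listed 6794880 barcodes without a filter on cells, so empty droplets were included. The submitters' processing notes name Cell Ranger 2.0 and the GRCz11 (danRer11) build, whereas the file headers of the matrices carry the version 3.1.0, and the annotation is not stated. The 47333 feature entries were summed to 30838 gene symbols. The labels' protocols name the 10x Genomics chemistry, and the labels give 3 wild-type (WT) libraries and 3 libraries of fish heterozygous for mpi (mpi+/-). Total UMIs per library ran from 79307462 to 91471334.

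Cells were called in each library from barcodes with at least 500 UMIs, at least 200 detected genes and at most 25% of UMIs from mitochondrially encoded genes. A barcode also had to lie at or above the knee of the barcode rank curve, or to reach a false discovery rate of 0.001 in a Dirichlet-multinomial test (50000 simulated profiles) against barcodes with at most 100 UMIs. Doublets were predicted with simulated doublets at a rate of 0.8% per 1000 cells and left out, and they made up 2.01% to 4.33% of the cells of a library. Cells were clustered on 2000 variable genes, 30 principal components and 20 neighbours with the Leiden method at resolution 1. Clusters were named from 13 fixed marker lists, with at least 3 markers at least 2-fold higher in the cluster, and a name ending in "-like" states that resemblance only. All libraries were clustered together without integration. Clusters whose mean profiles lay within a correlation distance of 0.15 were joined into groups, and cells outside the hepatocyte and erythroid groups were clustered again. This procedure was settled after clusters had been seen, because a first attempt mixed unlike cells. No genotype test had been looked at by then. Clusters with low UMIs and no marker among their 10 leading genes, or led by markers of a class other than that of their group, stayed unnamed, and their cells entered no class.

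Genotypes were compared on UMI counts summed per library and class, because libraries, and not cells, are the replicates. Classes needed at least 20 cells in a library, and at least 2 such libraries per genotype. The test was edgeR quasi-likelihood (robust, TMM normalisation, filterByExpr, genotype as the only term) with Benjamini-Hochberg adjustment at 0.05, and log2 fold changes are mpi+/- over WT. Standard errors were derived from the fold change and its F statistic. Shares of cells were compared by a two-sided exact permutation test over 20 relabellings, whose smallest possible p is 0.1. The 32 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over the lists of a class. Camera with an estimated correlation and fry were run beside it. In the WT libraries each class was set against the mean of the other classes with library as a term, over listed genes that are not markers of the class. The model took that mean on the log scale, whereas the CPM given for the other classes are arithmetic means. A log2 fold change there can therefore far exceed the ratio of the CPM.

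Genes were named by a fixed rule. It took mpi, up to 10 genes per direction (3 in the smaller classes and in all called cells) at an adjusted p of 0.05 with the 3 mpi+/- libraries all on one side of the 3 WT libraries, and up to 4 members per list. Where fewer than 5 genes passed, all were named, and where none passed, the 5 genes with the smallest p were given. In WT, the 2 genes with the smallest p per list and class were eligible. Members of lists that had passed no test of their own were picked after their values were seen, by smallest p.

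Alternatives fixed beforehand covered RLE size factors, a DESeq2 Wald test, genes with any count, a replicate block, leaving out each library, at least 1000 UMIs, at most 10% mitochondrial UMIs, predicted doublets kept, 2 times the Leiden resolution, and sums with the profile of the smallest barcodes subtracted. A vitellogenin covariate was also planned; the 7 vitellogenin genes summed to a log2 CPM (UMIs scaled to 1000000 per library) of 3.83, 2.82 and 1.81 in the WT libraries and 0.10, 0.45 and 1.89 in the mpi+/- libraries. Chosen after seeing the data were a factor for background, comparisons within each background group, single clusters of the stellate/mesenchymal-like and macrophage-like classes, all called cells without pancreas-like cells, and the sum over all barcodes. The background groups were set by the midpoint, 54.5285%, of the share of UMIs inside called cells. The planned gene fits of the neutrophil-like, erythroid-like, thrombocyte-like and B/plasma-like classes were not run for want of cells.

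The fits were tested on simulated data, in which 200 genes per class were changed 2-fold or 4-fold in counts drawn to match the libraries. Of 100 genes changed 4-fold, 62 were found in hepatocyte-like, 85 in stellate/mesenchymal-like, 94 in endothelial-like, 84 in macrophage-like, 19 in cholangiocyte-like and 94 in T/NK-like cells, and 17 in all called cells. Of 100 genes changed 2-fold, 8, 13, 27, 16, 1, 35 and 0 were found in the same order. False calls numbered 5, 5, 11, 7, 1, 9 and 0.

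The authors' 4 deposited cluster tables were described and not retested. They give log2 fold changes and detection as a fraction of cells, per the file headers and as the authors computed them, with the authors' adjusted p-value over pooled cells per the file headers. The joint fish and human table was used only for its number of clusters and entries. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.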

Results

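Livers of adult zebrafish were dissociated and read as single cells in 3 wild-type (WT) libraries and 3 libraries of siblings heterozygous for a mutant allele of mpi (mpi+/-). The gene mpi encodes mannose phosphate isomerase, which links glycolysis to the mannose used for N-glycosylation. The series asks which cells make up the healthy and the fibrotic fish liver. The WT libraries gave 3232, 2485 and 3958 called cells, and the mpi+/- libraries gave 5172, 4549 and 3093. Median UMIs per cell were 5705, 6126 and 13762.5 in WT and 7430, 8111 and 7287 in mpi+/-. The share of all UMIs that lay inside called cells was 40.2%, 34.1% and 74.7% in WT replicates 1 to 3 and 74.9%, 73.1% and 49.1% in mpi+/- replicates 1 to 3. WT replicates 1 and 2 and mpi+/- replicate 3 are called here the high-background libraries, and the other 3 the low-background libraries. The names refer only to UMIs outside called cells. Barcodes with at most 100 UMIs held 3.29%, 3.16% and 5.05% of the UMIs in WT and 5.66%, 5.88% and 3.08% in mpi+/-. By that measure the high-background group was the lower of the groups. Values within each of these groups compare 2 libraries with 1 and are given beside the pooled ones.

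The level of mpi differed little between genotypes. The gene had 35, 32 and 70 UMIs in the called cells of the WT libraries and 67, 52 and 45 in those of the mpi+/- libraries. Levels are given as CPM, UMIs scaled to 1000000 per library or class sum. For mpi they were 1.06 ± 0.0995 CPM in WT and 1.01 ± 0.14 in mpi+/- before normalisation, and 0.967 ± 0.0605 and 1.11 ± 0.178 after TMM normalisation (SD, n = 3), so the sign of the difference depends on the scaling. After normalisation the log2 fold change was 0.20 (SE 0.25) in all called cells and 0.13 (SE 0.21) in hepatocyte-like cells, with edgeR quasi-likelihood adjusted p of 0.885 and 0.820. Within the high-background libraries it was 0.19 in both, and within the low-background libraries it was 0.09 and 0.08. UMI counts from the 3′ end do not separate the alleles, so the level neither shows nor checks the genotype.

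Hepatocyte-like cells, which make plasma proteins and carry out most liver metabolism, formed 71.0% ± 4.7 of the WT cells (SD, n = 3). Cholangiocyte-like cells of the bile ducts formed 6.25% ± 3.88, macrophage-like cells 5.53% ± 4.08 and endothelial-like cells 4.62% ± 3.37. Stellate/mesenchymal-like cells, the retinoid-storing cells that lay down matrix in fibrosis, formed 3.05% ± 0.921. T/NK-like lymphocytes formed 3.01% ± 0.854 and erythroid-like cells 2.57% ± 1.44. Thrombocyte-like and neutrophil-like cells stood at 0.529% ± 0.0994 and 0.453% ± 0.346, and 2.87% ± 0.364 of the cells stayed unnamed. No cluster was named B/plasma-like at the resolution used, while at 2 times that resolution a cluster of 159 cells was, with 6 B/plasma markers at least 2-fold higher against 15 T/NK markers. These are shares of a cell suspension, which differ from shares in the tissue.

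**Figure D1:**
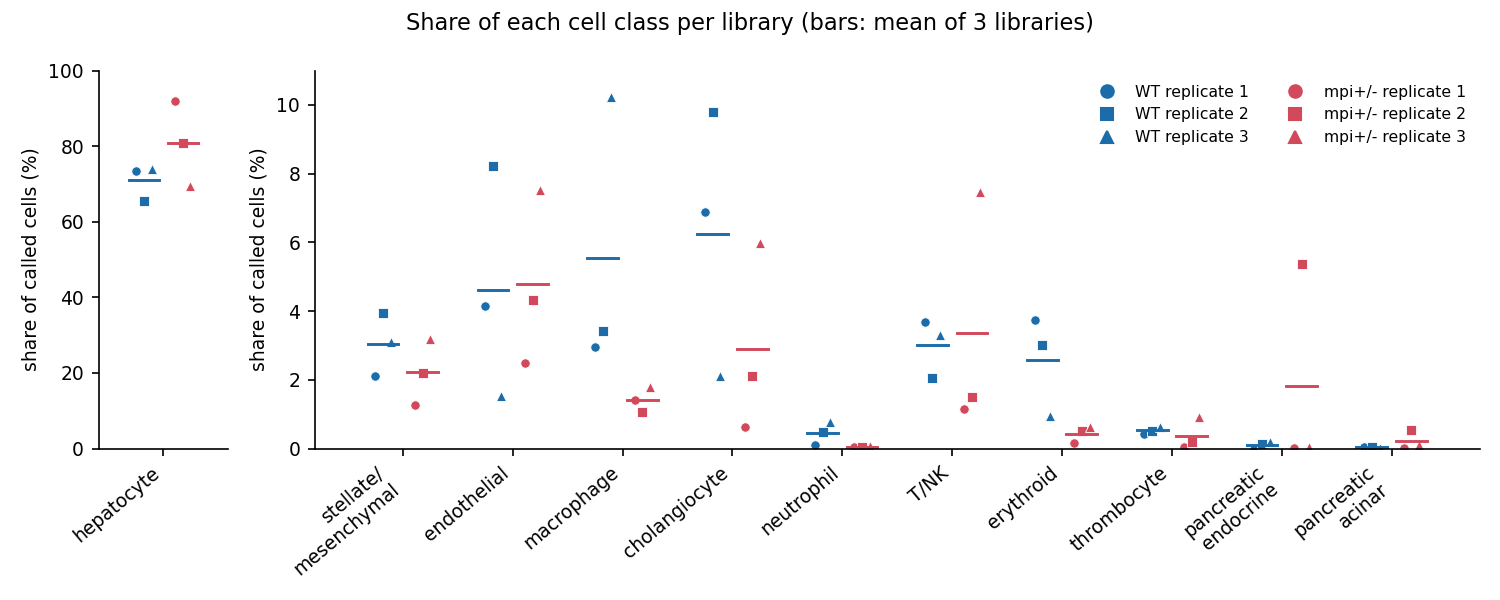
Share of called cells (vertical axis, %) by cell class, with a point per library (WT blue, mpi+/- red) and bars at the mean of 3. Macrophage-like cells reached 10.23% in WT replicate 3, and no class differed between genotypes at an adjusted p of 0.05 in the exact permutation test.

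In WT livers, 310 of the 613 listed genes tested were higher in hepatocyte-like cells than in the mean of the other classes, and 98 were lower, by edgeR quasi-likelihood tests. All 7 measured genes of bile acid metabolism were higher, and the list's median lay 4.71 log2 units above that of all tested genes. The sterol 12-alpha-hydroxylase gene cyp8b1 reached 242 ± 41.6 CPM (SD, n = 3) against a mean of 12.2 in the other classes (log2 6.04, SE 0.40). In all WT comparisons the log2 averages the other classes on the log scale, so it can exceed the ratio of the CPM. The glucose transporter gene slc2a2 had 226 ± 10.6 against 10.3 (log2 6.44, SE 0.34), and pcxb, for the pyruvate carboxylase of gluconeogenesis, had 91.1 ± 21 against 1.08 (log2 6.55, SE 0.32). Of 26 fatty acid oxidation genes 25 were higher, among them the carnitine palmitoyltransferase gene cpt1b at 133 ± 27.3 against 6.44, and of 70 oxidative phosphorylation genes 68 were higher. In the list that holds mpi, mannose and N-glycosylation, 14 of 18 tested genes were higher, with dolpp1 of the dolichol cycle at 84.2 ± 7.60 against 11.78 (log2 2.95, SE 0.24). The camera adjusted p was 9.45e-20 for oxidative phosphorylation, 1.67e-10 for fatty acid oxidation, 0.00495 for bile acid metabolism and 0.0119 for mannose and N-glycosylation. With an estimated correlation the adjusted p of these 4 lists by camera was 0.223 for the first 3 and 0.352 for the last. RLE size factors gave 228 genes higher and 132 lower, as the class median moved from 0.20 to −0.59, and background-subtracted sums gave 276 and 52.

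Within WT hepatocyte-like cells, mpi itself had 32, 21 and 62 UMIs, or 1.02, 0.952 and 0.975 CPM. Every other class held 0 to 6 UMIs of mpi per library, too few to rank the classes or to test the genotypes there.

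Stellate/mesenchymal-like cells of WT livers, summed over their clusters, had both their resting and their fibrogenic gene sets higher. These sums do not show whether the same cells carried both sets. All 8 measured retinoid and quiescence genes that are not class markers were higher, with the retinol dehydrogenase gene rdh10a at 70.8 ± 15.5 CPM against 0.633 (SD, n = 3; log2 8.36, SE 0.43) and the retinol-binding protein gene rbp5 at 473 ± 193 against 31.7 (log2 5.13, SE 0.40). Of 18 extracellular matrix genes 15 were higher. Of 17 genes of stellate activation and TGF-beta signalling 15 were higher, led by the matricellular gene thbs1a at 148 ± 7.73 against 0.933 (log2 9.75, SE 0.40). All 26 immediate early genes were higher as well. List medians lay above the class median by 5.27 for extracellular matrix (camera adjusted p = 5.56e-04), 4.77 for retinoid and quiescence (4.26e-04), 3.22 for activation and TGF-beta (1.15e-05) and 1.97 for immediate early genes (6.27e-06). With an estimated correlation the camera adjusted p was 0.232, 0.111, 0.0694 and 0.167. The endothelial and angiogenic list was higher too, by 4.98, in 23 of 26 genes (camera adjusted p = 2.41e-09, and 0.111 with an estimated correlation). The largest cluster of this class also carried endothelial markers, at a median of 0.572 times their highest level in the other stellate and endothelial clusters.

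Endothelial-like cells of WT livers, which line the sinusoids, had 147 of 645 listed genes higher and 105 lower. The angiogenic list stood 4.57 log2 units above the class median, with 14 of 18 genes higher (camera adjusted p = 5.72e-05, and 0.326 with an estimated correlation). The basement membrane collagen gene col4a2 had 213 ± 42.4 CPM against 28.1 (SD, n = 3; log2 8.90, SE 0.41), and the flow-responsive transcription factor gene klf2b was higher by log2 4.68 (SE 0.29). For col4a2 the log2 far exceeds the ratio of these CPM, as the other classes were averaged on the log scale. Of 11 matrix remodelling genes 9 were higher, by a median of 1.79 (camera adjusted p = 0.00312, and 0.257 with an estimated correlation). Without WT replicate 1, 107 genes were higher and 35 lower, without WT replicate 2, 96 and 39, and with background-subtracted sums 149 and 28.

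Macrophage-like cells of WT livers had higher antigen presentation and lysosomal genes, and the antigen presentation genes were higher in T/NK-like cells as well. The MHC class II invariant chain gene cd74b reached 3510 ± 113 CPM against 130 (SD, n = 3; log2 7.60, SE 0.47), and 4 of 5 tested genes of that list were higher. Of 20 macrophage activation and lysosome genes 13 were higher, with the transcription factor gene tfec at 164 ± 18.7 against 0.925 (log2 9.34, SE 0.44) and the cathepsin gene ctsh at 289 ± 43.2 against 18.9. Inflammatory genes included cxcl11.1 (log2 6.09, SE 0.34) and tnfb (log2 7.02, SE 0.41), with 12 of 21 higher. By camera the adjusted p was 0.0406 for MHC class II, 2.57e-04 for lysosome and 0.00241 for inflammatory genes, and 0.329, 0.1 and 0.1 with an estimated correlation. Of 638 listed genes 130 were higher and 195 lower, or 151 and 138 with RLE size factors, 116 and 97 without WT replicate 1, 118 and 95 without WT replicate 2, and 141 and 49 with background-subtracted sums.

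T/NK-like cells of WT livers had 87 of 653 listed genes higher and 116 lower, or 103 and 90 with RLE size factors. The lower count was 32 without WT replicate 1, 41 without WT replicate 2 and 48 with background-subtracted sums, beside 73, 76 and 85 higher. The nuclear receptor gene roraa had 47.9 ± 15.8 CPM against 1.1 (SD, n = 3; log2 6.80, SE 0.48), and the chemokine receptor gene cxcr4a was higher by log2 7.47 (SE 0.60). Of 18 interferon response genes 9 were higher, among them the immunoproteasome gene psmb9a (log2 2.73, SE 0.32), by a camera adjusted p of 0.00311 and 0.426 with an estimated correlation. Cholangiocyte-like cells had 158 of 655 listed genes higher and 67 lower. The glutathione peroxidase gene gpx1b reached 1157 ± 774 against 2.04 (log2 11, SE 0.48), and the BMP pseudoreceptor gene bambia 237 ± 22.0 against 42.3 (log2 4.89, SE 0.29). In those cells 13 of 21 TGF-beta genes were higher (camera adjusted p = 0.0266, and 0.687 with an estimated correlation). In cholangiocyte-like cells 103 genes were higher and 30 lower without WT replicate 2, 119 and 40 without WT replicate 1, and 165 and 21 with background-subtracted sums.

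Erythroid-like cells of WT livers had 151 of 654 listed genes higher and 132 lower, but many of the higher ones were hepatocyte genes. The mitophagy receptor gene bnip3lb, used in red cell maturation, had 233 ± 177 CPM against 36.0 (SD, n = 3; log2 2.80, SE 0.39). The hepatocyte gene fabp10a stood at 35696 ± 34663 against 32223, a standard deviation close to its mean. Subtracting the profile of the smallest barcodes removed 81.6% of the erythroid-like UMIs of WT replicate 3 and left 79 genes higher and 179 lower over the 3 libraries. Without that library 48 genes were higher and 193 lower, and 83 and 69 were lower without WT replicates 1 and 2. In all these WT comparisons the classes had been defined on the same counts, so their p-values are too small and rank genes only.

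**Figure D2:**
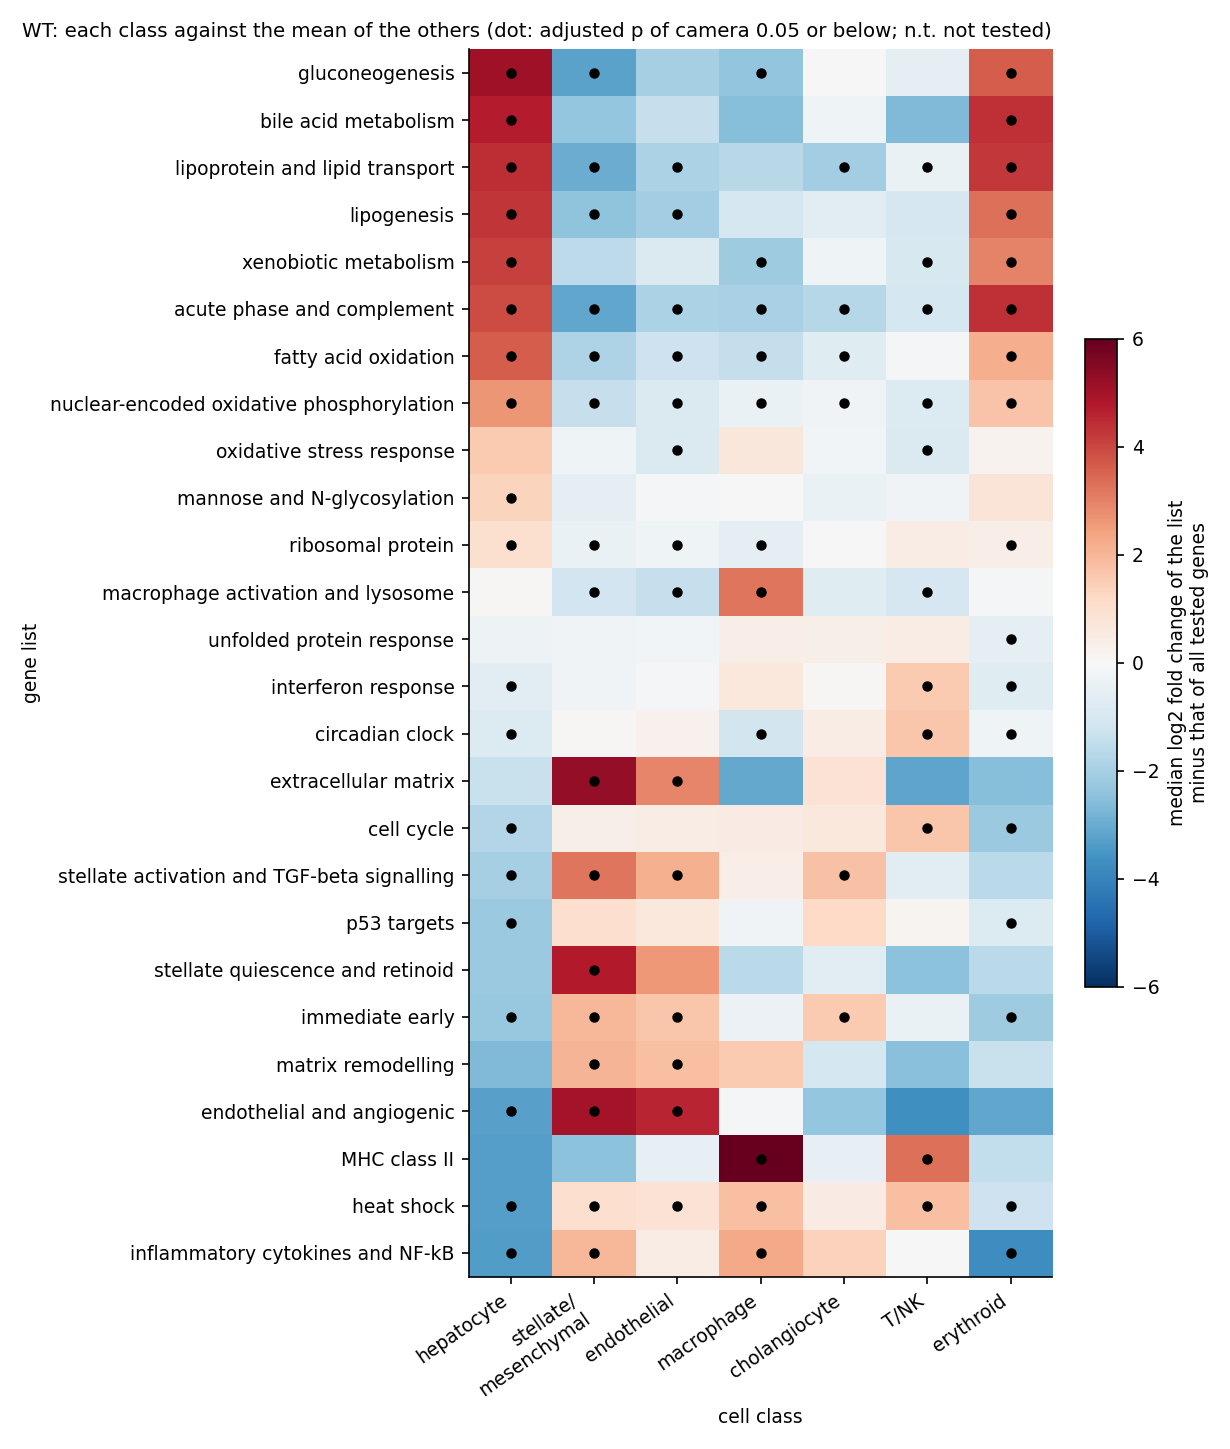
Heat map of the WT libraries with gene lists down and cell classes across, where colour gives the median log2 fold change of a list minus that of all tested genes in the class and dots mark a camera adjusted p of at most 0.05. Bile acid metabolism stands at 4.71 in hepatocyte-like cells and extracellular matrix at 5.27 in stellate/mesenchymal-like cells.

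Of all called cells, macrophage-like, neutrophil-like and erythroid-like cells made smaller shares in every mpi+/- library than in any WT library. The total matters here, as hepatocyte-like cells formed 91.9% of mpi+/- replicate 1. Without hepatocyte-like and erythroid-like cells in the total, the macrophage-like and neutrophil-like shares of that library exceeded those of WT replicate 1. Macrophage-like cells formed 5.53% ± 4.08 in WT and 1.41% ± 0.362 in mpi+/- (SD, n = 3; −4.12 percentage points; exact permutation p = 0.1, two-sided, adjusted 0.4). Erythroid-like cells stood at 2.57% ± 1.44 and 0.425% ± 0.240 (−2.15 points; exact p = 0.1, adjusted 0.4), and neutrophil-like cells at 0.453% ± 0.346 and 0.0555% ± 0.0106 (−0.397 points; exact p = 0.1, adjusted 0.4), which are 3, 12 and 31 cells in WT and 3, 2 and 2 in mpi+/-. With 3 libraries against 3 the test cannot go below 0.1, and 10% of random relabellings separate the groups fully. Within the high-background libraries the differences were −1.40, −2.77 and −0.223 points, and within the low-background libraries −9.0, −0.630 and −0.732. Without WT replicate 3 the macrophage-like difference was −1.77 points and the neutrophil-like difference −0.232. Of the macrophage-like cells, 346 of a cluster of 410 led by gpnmb, grn2 and grn1 came from WT replicate 3.

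Hepatocyte-like cells formed 71.0% ± 4.7 of WT and 80.7% ± 11.2 of mpi+/- cells (SD, n = 3; 9.72 points; exact permutation p = 0.3, adjusted 0.6). The difference was −0.0883 points within the high-background and 12.4 within the low-background libraries, and 4.123 without mpi+/- replicate 1 and 15.4 without mpi+/- replicate 3. Median UMIs were 1626, 2241, 2823 and 1843.5 in some clusters of this class, against 24873 in its largest. The cluster at 1626 held 1875 cells of mpi+/- replicate 1. These clusters kept their name because hepatocyte markers were among their 10 leading genes. Whether they hold droplets of background RNA was not tested beyond the calling of cells. Stellate/mesenchymal-like cells stood at 3.05% ± 0.921 and 2.23% ± 0.963 (−0.827 points; exact p = 0.5, adjusted 0.75), at 0.177 and −1.37 points within the groups. Their difference was −1.30 and −0.381 points without WT replicates 1 and 2, and −0.352 and −1.31 without mpi+/- replicates 1 and 3. Cholangiocyte-like cells stood at 6.25% ± 3.88 and 2.91% ± 2.76 (−3.34 points; exact p = 0.3, adjusted 0.6), at −2.34 and −0.723 within the groups, and at −1.57 and −5.41 without WT replicates 2 and 3 and −2.20 without mpi+/- replicate 1. Endothelial-like cells stood at 4.62% ± 3.37 and 4.79% ± 2.55 (0.162 points; exact p = 0.9, adjusted 0.982), at 1.36 and 1.9 within the groups. The endothelial-like difference was −0.0766, 1.96 and −1.39 without WT replicates 1, 2 and 3, and 1.31, 0.390 and −1.21 without mpi+/- replicates 1, 2 and 3. T/NK-like cells stood at 3.01% ± 0.854 and 3.37% ± 3.55 (0.360 points; exact p = 1, adjusted 1), at 4.60 and −1.98 within the groups. The T/NK-like difference was 0.693 and −0.121 without WT replicates 1 and 2, and 1.47, 1.3 and −1.69 without mpi+/- replicates 1, 2 and 3. Thrombocyte-like cells stood at 0.529% ± 0.0994 and 0.373% ± 0.466 (−0.156 points; exact p = 0.6, adjusted 0.8), at 0.427 and −0.524 within the groups and at 0.0113, −0.0573 and −0.422 without mpi+/- replicates 1, 2 and 3.

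Hepatocyte-like cells of mpi+/- livers had higher ribosomal protein, immediate early and gluconeogenic gene sets than those of WT livers, while no single gene passed. The ribosomal protein list rose by a median log2 of 0.62, with 80 of 85 members positive and 69 passing when adjusted over the list alone. Its members rpl37 and rps28 stood at 0.95 (SE 0.16) and 0.90 (SE 0.17). Immediate early genes rose by a median of 0.88, with 19 of 23 positive and 4 passing when adjusted over the list alone. The transcription factor genes egr1, fosab and fosl2 stood at 1.39 (SE 0.33), 1.23 (SE 0.25) and 1.61 (SE 0.33). Gluconeogenesis rose by a median of 0.53, with 8 of 12 positive and 2 passing over the list alone. It was led by pck1, for the rate-limiting phosphoenolpyruvate carboxykinase, at 1.29 (SE 0.25), and by tat, a glucocorticoid-induced aminotransferase gene, at 0.88 (SE 0.28). The camera adjusted p was 1.41e-25, 8.38e-08 and 0.0259, but 0.421, 0.419 and 0.419 with an estimated correlation, and fry, which asks only whether genes move one way, gave adjusted p of 0.113, 0.178 and 0.0745. Medians within the high-background and low-background libraries were 0.35 and 0.76 for ribosomal protein, 0.75 and 0.77 for immediate early, and 0.39 and 0.45 for gluconeogenesis genes. The gluconeogenesis call was lost without WT replicate 2 (camera adjusted p = 0.0578) and without mpi+/- replicate 3 (0.228). Named members of lists here and in the other classes were picked by smallest p after the values were seen.

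The list around mpi itself, mannose and N-glycosylation, fell in hepatocyte-like cells by a median log2 of −0.14, with 31 of 45 members negative and none passing when adjusted over the list alone. The mannosyltransferase gene alg1 stood at −1.44 (SE 0.32), the dolichol kinase gene dolk at −1.49 (SE 0.35) and mgat2 of N-glycan branching at −1.06 (SE 0.28). Cholesterol synthesis fell by −0.35 (15 of 19 members negative), with the sterol reductase gene tm7sf2 at −1.20 (SE 0.42). The interferon response fell by −0.24 (19 of 29 negative), with the immunoproteasome genes psmb10 at −1.38 (SE 0.33) and psmb9a at −1.0 (SE 0.30). Retinoid genes of the quiescence list fell by −0.41 (5 of 6 negative), with rdh10b at −0.79 (SE 0.20). Glycolysis rose by 0.24 (18 of 26 positive), with gapdh at 0.87 (SE 0.17), and TGF-beta signalling rose by 0.18 (13 of 20 positive). Each of these 6 lists had a camera adjusted p of 0.0484, and 0.419 to 0.838 with an estimated correlation. Median values within the high-background and low-background libraries were −0.04 and −0.28 for mannose, −0.74 and −0.10 for cholesterol, −0.02 and −0.38 for interferon, −0.64 and −0.45 for retinoid, 0.23 and 0.29 for glycolysis, and 0.39 and 0.18 for TGF-beta genes.

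Each of these 6 hepatocyte calls was lost without at least 2 of the libraries. By camera, mannose and N-glycosylation had an adjusted p of 0.0515 without WT replicate 1, 0.470 without WT replicate 3, 0.194 without mpi+/- replicate 2 and 0.228 without mpi+/- replicate 3. Cholesterol synthesis had a camera adjusted p of 0.0836 without WT replicate 2 and 0.109 without mpi+/- replicate 3. Interferon response had a camera adjusted p of 0.154 without WT replicate 2, 0.0735 without WT replicate 3, 0.278 without mpi+/- replicate 1 and 0.129 without mpi+/- replicate 2. For glycolysis, camera adjusted p were 0.0808, 0.0836 and 0.129 without WT replicates 1, 2 and 3, and 0.124 and 0.228 without mpi+/- replicates 2 and 3. For the retinoid list, camera adjusted p were 0.0603, 0.0759 and 0.147 without WT replicates 1, 2 and 3, and 0.0948 and 0.228 without mpi+/- replicates 1 and 3. For TGF-beta signalling, camera adjusted p were 0.0603, 0.243 and 0.0586 without WT replicates 1, 2 and 3, and 0.0674 and 0.388 without mpi+/- replicates 1 and 3. With background as a factor, cholesterol synthesis and interferon response stood at camera adjusted p of 0.0882 and 0.137. Vitellogenin, the egg yolk precursor made under oestrogen, stood at a log2 CPM of 3.83, 2.82 and 1.81 in the WT libraries and 0.10, 0.45 and 1.89 in the mpi+/- libraries. The labels do not give the sex of the fish, and the 7 vitellogenin genes held 72 to 504 UMIs per library. With that level as a covariate, cholesterol synthesis and interferon response had camera adjusted p of 0.164 and 0.668. The level was higher in WT replicates 1 and 2 than in any mpi+/- library, so this covariate overlaps with genotype. A call lost with it, here or in the other classes, cannot be assigned to vitellogenin rather than genotype. By fry only the retinoid list passed (adjusted p = 0.0113). In all, 9 of 29 lists passed, and 5, 3 and 5 passed without WT replicates 1, 2 and 3, and 3 without mpi+/- replicate 3.

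Of 10582 genes tested in hepatocyte-like cells, 0 passed by edgeR quasi-likelihood at a Benjamini-Hochberg adjusted p of 0.05, 1498 had an unadjusted p under 0.05, and DESeq2 called 252 higher and 114 lower. The 5 genes with the smallest p follow. The inhibitory Smad gene smad7, a brake on TGF-beta signalling, had 3.05 ± 0.253 CPM in WT and 7.94 ± 0.241 in mpi+/- (SD, n = 3; log2 1.38, SE 0.14, edgeR adjusted p = 0.0768; 1.5 and 1.22 within the background groups). The uncharacterised gene zgc:154040 had 3.90 ± 0.204 and 0.876 ± 0.0885 (log2 −2.15, SE 0.18, edgeR adjusted p = 0.0608; −2.15 and −2.13). The myosin light chain kinase gene mylka had 4.1 ± 1.1 and 0.471 ± 0.179 (log2 −3.11, SE 0.36, edgeR adjusted p = 0.0882; −3.08 and −3.15). The actin regulator gene phactr2 had 0.634 ± 0.153 and 4.18 ± 1.32 (log2 2.75, SE 0.32, edgeR adjusted p = 0.0882; 2.05 and 3.22). The myosin light chain gene myl10 had 51, 50 and 102 UMIs in WT and 0 in each mpi+/- library, at least 28.9-fold lower at a floor of 3 counts per library (edgeR adjusted p = 0.0608). Counts of passing genes without 1 library were 2 without WT replicate 2, 1 without mpi+/- replicates 1 or 2, and 3 without mpi+/- replicate 3. Hepatocyte-like clusters split by library: a cluster of 2536 cells held 2530 from mpi+/- replicate 1, and another of 2367 held 2313 from WT replicate 3.

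Stellate/mesenchymal-like cells of mpi+/- livers had lower oxidative phosphorylation, matrix, retinoid and complement gene sets by camera at the preset correlation only. At least as many lists were called in 6 of the 10 splits of the libraries into 3 and 3, the real one included. Oxidative phosphorylation fell by a median log2 of −0.28 (49 of 62 members negative, 1 passing when adjusted over the list alone), with ndufs3 at −2.74 (SE 0.65). Extracellular matrix fell by −0.33 (20 of 28 negative, 0 over the list alone), with the basement membrane genes col18a1a at −1.21 (SE 0.35) and col4a2 at −0.54 (SE 0.22). Quiescence and retinoid genes fell by −0.26 (9 of 12 negative, 3 over the list alone), with lrata, the enzyme that esterifies retinol for storage, at −1.84 (SE 0.43) and rbp5 at −1.08 (SE 0.31). Acute phase and complement genes fell by −0.28 (18 of 25 negative, 1 over the list alone), with the complement inhibitor gene cfi at −1.14 (SE 0.29), and the hepatocyte markers tfa and fabp10a stood at −0.82 (SE 0.27) and −0.48 (SE 0.24). The activation and TGF-beta list had a median of 0.24 over 22 genes and did not pass (camera adjusted p = 0.366). The camera adjusted p of the 4 lists was 1.01e-05, 0.00457, 0.0287 and 0.0287, and 0.641, 0.5, 0.641 and 0.641 with an estimated correlation. Median values within the high-background and low-background libraries were −0.59 and −0.19, −0.22 and −0.56, −0.54 and −0.32, and 0.22 and −0.60, so complement genes differed in sign.

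Only 1 of 4329 genes passed in stellate/mesenchymal-like cells, the erythroid marker si:ch211-250g4.3, with 750 ± 207 CPM in WT and 90.3 ± 24.7 in mpi+/- (SD, n = 3; log2 −3.06, SE 0.29, edgeR adjusted p = 1.07e-04; −3.13 and −3.25 within the background groups). An unadjusted p under 0.05 was reached by 326 genes, and DESeq2 called 2 higher and 3 lower. At 2 times the cluster resolution si:ch211-250g4.3 stood at −1.84 (edgeR adjusted p = 0.592), as 36 cells of the class (32 WT, 4 mpi+/-) left it for a mixed cluster led by globin genes. Those cells held 70.7% of the UMIs of this gene in the class. In the largest cluster of the class alone it stood at −3.00 and was the only gene to pass. Without that cluster it kept too few counts to be tested, and 1 of 926 genes passed, which did not pass in the whole class. Counts of passing genes were 2 without WT replicate 2, 2 without mpi+/- replicate 1, 3 without mpi+/- replicate 2 and 5 without mpi+/- replicate 3. The extracellular matrix call was lost without mpi+/- replicate 1 (camera adjusted p = 0.151). The quiescence and retinoid call was lost without WT replicates 1 and 3 and mpi+/- replicate 3 (camera adjusted p = 0.0530, 0.153 and 0.219). The acute phase and complement call was lost without WT replicate 1 and mpi+/- replicates 1 and 2 (camera adjusted p = 0.0530, 0.275 and 0.243) and with background as a factor (0.141). With background-subtracted sums its camera adjusted p was 0.153, and with the vitellogenin level as a covariate it was 0.949, at a median of 0.19, and 0.119 for extracellular matrix. By fry the 4 lists had adjusted p of 0.423 to 0.529. Of 27 lists 4 passed, and 2 passed without WT replicate 1.

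Endothelial-like cells of mpi+/- livers had 7 of 3548 genes lower and none higher. The globin genes hbba2, ba1l and ba1, made by red cells, fell from 104 ± 28.9 to 9.5 ± 0.446, from 347 ± 85.5 to 42.7 ± 23.3 and from 907 ± 384 to 130 ± 54.6 CPM (SD, n = 3). Their log2 fold changes were −3.50 (SE 0.34), −2.93 (SE 0.35) and −2.76 (SE 0.41), with edgeR quasi-likelihood adjusted p of 7.33e-05, 0.00130 and 0.0387. The mitochondrial ribosomal RNA genes mt-rnr2 and mt-rnr1 fell by log2 −0.98 (SE 0.16, 82422 ± 2788 to 41900 ± 10421 CPM) and −0.86 (SE 0.16, 7517 ± 718 to 4134 ± 597), with edgeR adjusted p of 0.0199 and 0.0387. The oxygen-binding myoglobin gene mb fell by −1.06 (SE 0.20, 2309 ± 307 to 1106 ± 238) and the calcium-binding gene icn by −1.91 (SE 0.34, 308 ± 131 to 86.0 ± 32.4), both at an edgeR adjusted p of 0.0387. The gene icn is among the fixed cholangiocyte markers, and cholangiocyte-like cells formed 6.25% of WT and 2.91% of mpi+/- cells. Whether its RNA came from the endothelial-like cells themselves was not tested. Within the high-background and low-background libraries hbba2 stood at −3.66 and −2.83, ba1l at −2.75 and −3.19, ba1 at −2.45 and −3.22, mt-rnr2 at −0.60 and −1.20, mt-rnr1 at −0.62 and −1.06, mb at −0.91 and −1.04, and icn at −2.07 and −1.12. The median mitochondrial share of all called cells was 7.42%, 7.88% and 3.16% in WT and 3.39%, 2.25% and 5.11% in mpi+/-.

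The calls of hbba2 and ba1l in endothelial-like cells held without each library in turn, and 2 of the 7 genes passed without WT replicate 2. Both were lost with the vitellogenin level, which overlaps with genotype, as a covariate (edgeR adjusted p = 0.128 each). With background-subtracted sums none of the 7 passed, as ba1l had an edgeR adjusted p of 0.134 and hbba2 kept too few counts to be tested. The edgeR adjusted p of mt-rnr2 was 0.0625, 0.629 and 0.0941 without WT replicate 2, WT replicate 3 and mpi+/- replicate 1. That of ba1 by edgeR was 0.108, 0.160, 0.0867 and 0.157 without WT replicates 2 and 3 and mpi+/- replicates 2 and 3. For mt-rnr1 the edgeR adjusted p was 0.128, 0.0975, 0.0867 and 0.0841 without WT replicate 2 and mpi+/- replicates 1, 2 and 3. For mb the edgeR adjusted p was 0.106, 0.108, 0.190 and 0.0841 without WT replicates 1 and 2 and mpi+/- replicates 1 and 3. For icn the edgeR adjusted p was 0.0687, 0.108, 0.0867 and 0.157 without WT replicates 1 and 2 and mpi+/- replicates 2 and 3. With background as a factor, mt-rnr2, ba1, mt-rnr1, mb and icn had edgeR adjusted p of 0.0736, 0.0985, 0.0736, 0.128 and 0.222. In the same order the edgeR adjusted p was 0.834, 0.185, 0.725, 0.834 and 0.834 with the vitellogenin covariate, and 0.128, 0.571, 0.0671, 0.0671 and 0.112 with background-subtracted sums. In cells with at most 10% mitochondrial UMIs, mt-rnr2 stood at −0.62 and mt-rnr1 at −0.57 (edgeR adjusted p = 0.199 and 0.376). Both genes count toward that mitochondrial share, so the limit itself caps their level and cannot test their difference independently. In the same cells ba1 and icn had edgeR adjusted p of 0.0772 and 0.108. For ba1 it was 0.0579 at 2 times the cluster resolution. DESeq2 called 3 genes higher and 13 lower. An unadjusted p under 0.05 was reached by 307 genes.

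Oxidative phosphorylation genes encoded in the nucleus fell in endothelial-like cells by a median log2 of −0.35, with 56 of 61 members negative. The ATP synthase genes atp5j and atp5a1 stood at −0.67 (SE 0.26) and −0.60 (SE 0.24). Immediate early genes rose by 0.25 (19 of 22 positive), with the AP-1 genes junba at 0.45 (SE 0.15) and jun at 0.41 (SE 0.16). Lipoprotein genes fell by −0.46 (11 of 12 negative), with apoa4b.1 at −1.36 (SE 0.45) and the hepatocyte marker fabp10a at −0.59 (SE 0.25). In each of the 3 lists 0 members passed when adjusted over the list alone. Adjusted p by camera was 1.08e-07, 0.0279 and 0.0315, and 0.571, 0.571 and 0.581 with an estimated correlation. Median values within the high-background and low-background libraries were −0.45 and −0.45, 0.41 and 0.28, and −0.52 and 0.25. The immediate early call in these cells was lost without WT replicate 1 and mpi+/- replicate 3 (camera adjusted p = 0.179 and 0.109), and with background as a factor (0.0522). The lipoprotein call was lost without WT replicates 1 and 2 and mpi+/- replicates 1, 2 and 3 (camera adjusted p = 0.997, 0.130, 0.0969, 0.332 and 0.0693). With the vitellogenin covariate, immediate early and lipoprotein genes had camera adjusted p of 0.285 and 0.581, the latter at a median of 0.13. By fry the 3 lists had adjusted p of 0.342 to 0.508. Of 27 lists 3 passed, 1 without WT replicate 1 and 5 without WT replicate 3. At least as many were called in 5 of the 10 splits of the libraries, the real one included.

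**Figure D3:**
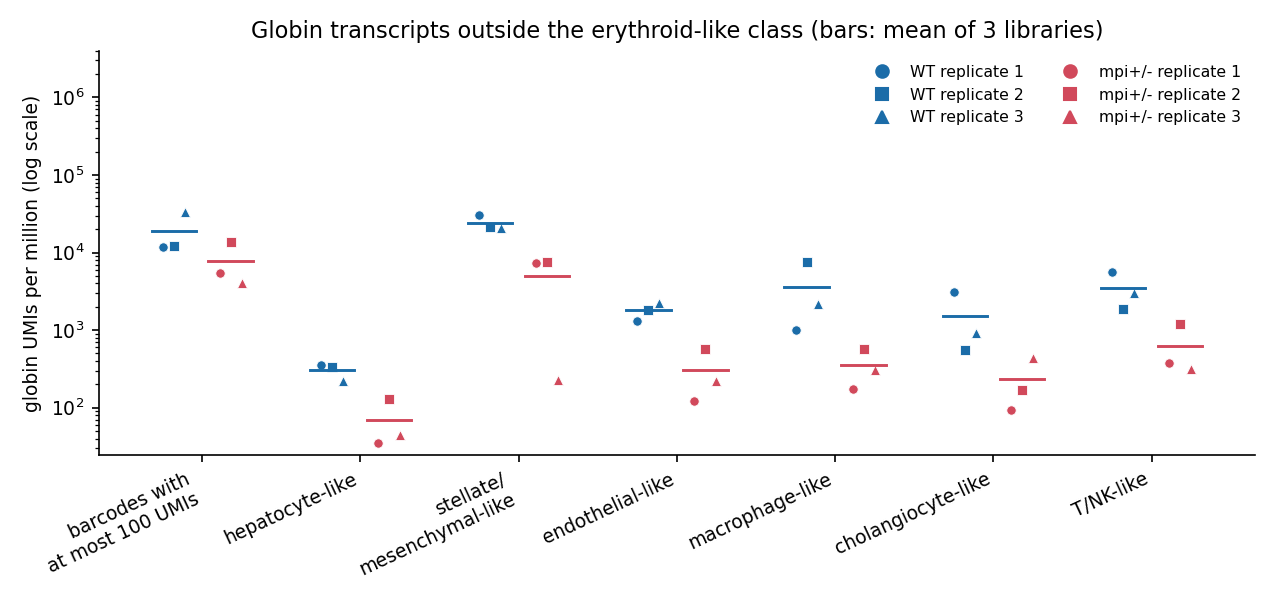
Summed CPM of 11 globin genes (vertical log axis) in barcodes with at most 100 UMIs and in 6 cell classes, with a point per library (WT blue, mpi+/- red) and bars at the mean of 3. In endothelial-like cells they average 1795 in WT and 303 in mpi+/-, and in hepatocyte-like cells 304 and 69.7.

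Macrophage-like cells of mpi+/- livers had lower oxidative phosphorylation genes, by a median log2 of −0.36 with 44 of 51 members negative and 0 passing when adjusted over the list alone. The cytochrome oxidase gene cox5ab stood at −1.53 (SE 0.54) and the ATP synthase gene atp5o at −0.98 (SE 0.33). The camera adjusted p was 8.67e-05, and 0.828 with an estimated correlation or 0.349 by fry; medians were −0.21 and −0.52 within the background groups. Of 2176 genes 0 passed by edgeR quasi-likelihood at a Benjamini-Hochberg adjusted p of 0.05, 138 had an unadjusted p under 0.05, and DESeq2 called 0 higher and 3 lower. The 5 smallest p belonged to the haem-regulated repressor gene bach1b (104 ± 26.8 CPM in WT and 259 ± 42.2 in mpi+/-, SD, n = 3; log2 1.29, SE 0.29), the p53-induced gene tp53inp1 (64.9 ± 17.2 and 170 ± 35.06; 1.36, SE 0.32), the actin-binding gene pfn1 (6549 ± 725 and 4173 ± 538; −0.65, SE 0.16), mt-rnr1 (11798 ± 789 and 7116 ± 1743; −0.73, SE 0.18) and the proteasome gene psmc3 (24.4 ± 1.69 and 62.6 ± 9.64; 1.36, SE 0.35). Each had an edgeR adjusted p of 0.700. Only 1 of 25 lists passed, with 2 without WT replicate 1, 3 without WT replicate 3 and 3 without mpi+/- replicate 1. At least as many were called in 8 of the 10 splits of the libraries, the real one included.

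Cholangiocyte-like cells of mpi+/- livers had lower acute phase, lipoprotein, unfolded protein response and oxidative stress gene sets by camera at the preset correlation only. At least as many lists were called in 8 of the 10 splits of the libraries, the real one included. Acute phase and complement genes fell by a median log2 of −0.65 (21 of 25 negative), with irg1l, an itaconate-forming enzyme gene of inflammation, at −2.29 (SE 0.46; 43.7 ± 18.7 and 9.42 ± 2.22 CPM, SD, n = 3). Lipoprotein genes fell by −0.70 (15 of 16 negative), with apoa1b at −1.17 (SE 0.47). The hepatocyte marker fabp10a stood at −1.06 (SE 0.48), and the share of UMIs removed as background by hepatocyte markers was 7.67%, 4.84% and 3.55% in WT and 4.84%, 2.33% and 4.24% in mpi+/-. Unfolded protein response genes fell by −0.26 (19 of 29 negative), with the chaperone gene hsp90b1 at −0.99 (SE 0.41). Oxidative stress genes fell by −0.27 (16 of 20 negative), with the haem oxygenase gene hmox1a at −0.92 (SE 0.38). When adjusted over the list alone 1, 0, 1 and 0 members passed. Camera gave an adjusted p of 1.79e-04, 9.76e-04, 0.00927 and 0.0181, and 0.679, 0.833, 0.852 and 0.679 with an estimated correlation. Median values within the high-background and low-background libraries were −0.45 and −0.40, −0.90 and −0.10, −0.65 and 0.14, and −0.34 and −0.21.

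No single list of cholangiocyte-like cells held throughout. Acute phase and complement was lost without WT replicate 1 (camera adjusted p = 0.210, median −0.15). Lipoprotein was lost without WT replicate 1 and mpi+/- replicate 2 (camera adjusted p = 0.253 and 0.18). Unfolded protein response was lost without WT replicates 1 and 2 and mpi+/- replicates 2 and 3 (camera adjusted p = 0.145, 0.153, 0.198 and 0.615). Oxidative stress was lost without WT replicate 2 and mpi+/- replicates 1 and 3 (camera adjusted p = 0.260, 0.236 and 0.101) and with background as a factor (0.0538). With the vitellogenin covariate, acute phase, lipoprotein and oxidative stress genes had camera adjusted p of 0.606, 0.945 and 0.202, with acute phase at a median of 0.11. With background-subtracted sums lipoprotein and oxidative stress genes had camera adjusted p of 0.451 and 0.0889. By fry the 4 lists had adjusted p of 0.386 to 0.663. Of 28 lists 4 passed, and 1, 2 and 2 passed without WT replicate 1, WT replicate 2 and mpi+/- replicate 2. Of 4510 genes 0 passed by edgeR quasi-likelihood at a Benjamini-Hochberg adjusted p of 0.05, with 1 without mpi+/- replicate 1, 137 had an unadjusted p under 0.05, and DESeq2 called 0 higher and 4 lower. The smallest p were those of the globin genes ba1 (516 ± 339 and 51.1 ± 8.48 CPM, SD, n = 3; log2 −3.31, SE 0.51) and ba1l (−3.59, SE 0.67), of irg1l, of the erythroid gene si:ch211-5k11.8 (−3.82, SE 0.80) and of the chaperone gene dnajb9b (−3.28, SE 0.72). Their edgeR adjusted p was 0.533 for ba1 and 1.00 for the others. The 33 cells of mpi+/- replicate 1 were the fewest of any library in this class.

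T/NK-like cells of mpi+/- livers had lower ribosomal protein and higher cell cycle gene sets by camera at the preset correlation only. At least as many lists were called in 7 of the 10 splits of the libraries, the real one included. Ribosomal protein genes fell by a median log2 of −0.19 (56 of 68 negative, 0 passing when adjusted over the list alone), with rpl15 at −0.38 (SE 0.13) and rps6 at −0.35 (SE 0.12). All 6 measured cell cycle genes were positive, at a median of 0.75 (1 over the list alone), with the tubulin gene tuba8l4 at 1.17 (SE 0.30) and the replication clamp gene pcna at 0.91 (SE 0.37). The camera adjusted p was 1.53e-06 and 0.00415, and 0.834 and 0.599 with an estimated correlation; medians within the background groups were −0.28 and −0.17, and 0.23 and 1.06. The cell cycle call was lost without mpi+/- replicate 2 (camera adjusted p = 0.297, median 0.25) and with the vitellogenin covariate (0.558), and by fry both lists had adjusted p of 0.453 and 0.114. Of 1218 genes 1 passed, the globin gene ba1l, which fell from 696 ± 258 to 92.5 ± 41.8 CPM (SD, n = 3; log2 −3.00, SE 0.39, edgeR adjusted p = 0.0166; −3.67 and −2.39 within the background groups). That call was lost without WT replicate 1 and mpi+/- replicates 1 and 3 (edgeR adjusted p = 0.0650, 0.174 and 0.239), with background-subtracted sums (0.251) and with the vitellogenin covariate (0.122). Counts were 2 without WT replicate 3 and 4 without mpi+/- replicate 2. An unadjusted p under 0.05 was reached by 75 genes, and DESeq2 called 1 higher and 3 lower. Of 19 lists 2 passed, and 4 passed without WT replicate 3 or mpi+/- replicate 3.

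Over all called cells, mpi+/- livers had higher ribosomal protein and gluconeogenesis and lower macrophage, inflammatory and retinoid gene sets by camera at the preset correlation only. These sums mix classes, and macrophage-like cells formed 5.53% of WT and 1.41% of mpi+/- cells. At least as many lists were called in 6 of the 10 splits of the libraries, the real one included. Ribosomal protein genes rose by a median log2 of 0.67 (81 of 86 positive) and gluconeogenesis by 0.42 (11 of 14 positive), with pck1 at 1.37 (SE 0.29). Macrophage activation and lysosome genes fell by −0.58 (22 of 29 negative), with the scavenger receptor gene marco at −1.90 (SE 0.28). Inflammatory genes fell by −0.55 (29 of 34 negative), with the granulocyte colony-stimulating factor gene csf3b at −2.58 (SE 0.31). Retinoid and quiescence genes fell by −0.64 (12 of 14 negative), with lrata at −2.05 (SE 0.46). When adjusted over the list alone 0, 1, 3, 1 and 1 members passed in this order. By camera the adjusted p was 2.09e-23, 0.00376, 8.27e-06, 3.22e-05 and 3.86e-04, and 0.560, 0.394, 0.394, 0.560 and 0.394 with an estimated correlation. All 5 calls held without each library in turn, and medians within the high-background and low-background libraries were 0.26 and 0.75, 0.36 and 0.43, −0.31 and −0.67, −0.16 and −0.80, and −0.49 and −0.43. With the vitellogenin covariate, gluconeogenesis, retinoid and inflammatory genes had camera adjusted p of 0.0587, 0.0567 and 0.334, and by fry the 5 lists had adjusted p of 0.109 to 0.370.

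A further 5 lists passed over all called cells, each with a weaker footing. Matrix remodelling fell by −0.46 (14 of 18 negative, 3 passing over the list alone), with the membrane protease gene mmp14b at −1.30 (SE 0.27). The interferon response fell by −0.20 (25 of 33 negative), cytotoxic lymphocyte genes by −1.34 (5 of 7 negative) and cell cycle genes by −0.27 (17 of 25 negative). Xenobiotic metabolism rose by 0.16 (39 of 54 positive), with the cytochrome gene cyp2ad6 at 1.66 (SE 0.47). When adjusted over the list alone 0 members of these last 4 lists passed. The camera adjusted p was 0.00241 for matrix remodelling, 0.0136 for interferon, 0.0214 for cytotoxic, 0.0356 for cell cycle and 0.0356 for xenobiotic genes, and 0.560 to 0.734 with an estimated correlation. Within the high-background libraries the median was 0.02 for matrix remodelling, 0.05 for interferon, 0.05 for cytotoxic, 0.10 for cell cycle and 0.26 for xenobiotic genes, against −0.38, −0.34, −0.93, −1.09 and 0.04 within the low-background libraries. Matrix remodelling was lost without mpi+/- replicate 1 (camera adjusted p = 0.0740), and interferon without mpi+/- replicates 1 and 2 (0.224 and 0.0927). Cytotoxic genes were lost without WT replicate 2 and mpi+/- replicates 1 and 2 (camera adjusted p = 0.146, 0.155 and 0.101), and cell cycle without WT replicate 3 and mpi+/- replicate 1 (0.199 and 0.637). Xenobiotic genes were lost without WT replicates 1 and 2 and mpi+/- replicate 1 (camera adjusted p = 0.105, 0.0635 and 0.224). With background as a factor, cell cycle and xenobiotic genes stood at camera adjusted p of 0.0657 and 0.132, and with the vitellogenin covariate all 5 lists had camera adjusted p of 0.315 to 0.709, with interferon at a median of 0.18 and xenobiotic genes at −0.09. By fry they had adjusted p of 0.370 to 0.630. Without mpi+/- replicate 3, 16 of 30 lists passed against 10 with all libraries.

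Over all called cells 0 of 13426 genes passed by edgeR quasi-likelihood at a Benjamini-Hochberg adjusted p of 0.05, 1128 had an unadjusted p under 0.05, and DESeq2 called 84 higher and 126 lower. The haem oxygenase gene hmox1a had 76.9 ± 9.63 CPM in WT and 15.6 ± 2.39 in mpi+/- (SD, n = 3; log2 −2.30, SE 0.21, edgeR adjusted p = 0.121; −2.05 and −2.52 within the background groups). The mitochondrial carrier gene slc25a1a had 1.63 ± 0.365 and 0.109 ± 0.0102 (log2 −3.87, SE 0.33, edgeR adjusted p = 0.121). The kidney injury molecule gene havcr1 had 5.82 ± 0.675 and 1.29 ± 0.317 (log2 −2.17, SE 0.25, edgeR adjusted p = 0.147), and zgc:153911 had 72.0 ± 5.51 and 13.7 ± 4.01 (log2 −2.39, SE 0.26, edgeR adjusted p = 0.147). Both hmox1a and havcr1 are among the fixed macrophage markers, and macrophage-like cells formed 5.53% of WT and 1.41% of mpi+/- cells. These sums cannot separate cell makeup from levels per cell. For myl10, 55, 55 and 112 UMIs in WT stood against 0 in each mpi+/- library, at least 30.2-fold lower at a floor of 3 counts (edgeR adjusted p = 0.121).

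**Figure D4:**
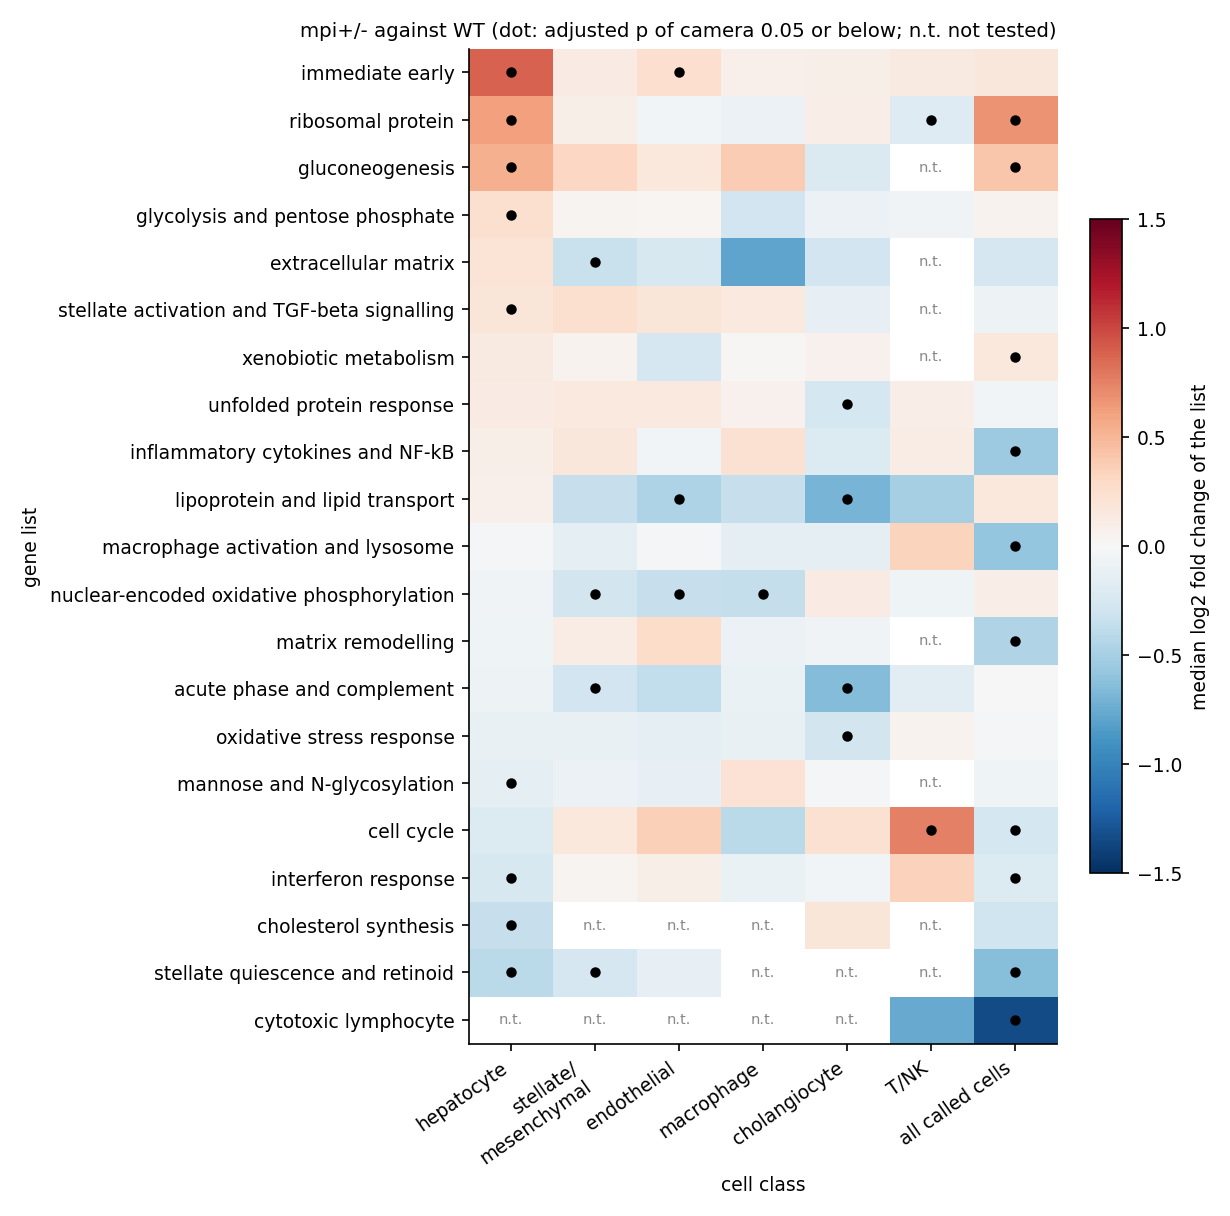
Heat map of mpi+/- against WT with gene lists down and cell classes and all called cells across, where colour gives the median log2 fold change of a list, dots mark a camera adjusted p of at most 0.05, and n.t. marks lists not tested. Ribosomal protein genes stand at 0.62 in hepatocyte-like cells and −0.19 in T/NK-like cells, and oxidative phosphorylation is negative with a dot in stellate, endothelial and macrophage-like cells. The dots use a preset correlation, and no list passed by camera with an estimated correlation.

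The authors' deposited tables name 19 clusters in the WT atlas, 20 in WT and mpi+/- together, 13 in an endothelial and stellate subset and 21 in a joint table of fish and human. In the table of both genotypes, the endothelial and stellate cluster zEC/HSC was led by socs3a (authors' log2 fold change 5.18), the inflammatory macrophage cluster by cd74a (5.54) and the pancreatic cluster zPan by gcga (9.59). Among the 50 leading genes per cluster, the erythroid-like cluster made here shared 30 with zEry, a T/NK-like cluster 29 with zNK/T1, and an endothelial-like cluster 28 with zEC1. The largest stellate/mesenchymal-like cluster shared 22 with zEC-HSC and 17 with zHSC. The hepatocyte-like cluster of 2536 cells shared 6 with zHep1.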

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

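The globin test in the smallest barcodes and the multiplet test were fixed before their values were seen, and the other tests given here, with the rule that the globin test also hold without each library, were chosen after results were seen.

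Globin genes were lower in mpi+/- outside the erythroid-like class, with log2 differences of −2.35 in hepatocyte-like, −3.35 in stellate/mesenchymal-like (−1.68 without mpi+/- replicate 3), −2.82 in endothelial-like, −3.03 in macrophage-like, −2.60 in cholangiocyte-like and −2.60 in T/NK-like cells (exact permutation p = 0.1 each, n = 3). Of the globin UMIs of stellate/mesenchymal-like cells 93.7% lay in 36 cells (32 WT, 4 mpi+/-) that formed a mixed cluster at 2 times the resolution, and without them the difference was −2.49 (1633 ± 709 against 294 ± 138 CPM, SD). Free or attached erythroid RNA, in proportion to the red cells of a library, would lower globins in barcodes with at most 100 UMIs as well, where the log2 difference was −1.33 (19165 ± 12487 against 7695 ± 5093 CPM, SD; exact permutation p = 0.3) but −0.83 without WT replicate 3, whose level was the highest beside an erythroid-like share of 0.960% against 3.74% and 3.02% in WT replicates 1 and 2, so that source remains open. In stellate/mesenchymal-like cells hepatocyte markers left room for at most 6.26% of the globin UMIs of a WT library. Background RNA was thus excluded as the whole source of globins in the class. That bound rests on the mixed cells, which held 19880 of 20521, 21641 of 22945 and 20273 of 22517 globin UMIs in WT. Background could give 427, 619 and 1409 UMIs in those libraries, so it remains open for the other cells and their difference of −2.49. In endothelial-like cells hbba2 and ba1l kept an edgeR adjusted p of at most 0.0248 with background as a factor. That factor marks the share of UMIs inside called cells, not the globin content of the background, so it cannot decide on background as the cause. Hepatocyte markers left room for at most 68.6%, 41.5% and 55.3% of the globin UMIs there in WT, and 235%, 110% and 88.1% in mpi+/-. With background-subtracted sums ba1l went from −2.93 (SE 0.35) to −5.28 (SE 0.79) and lost its call on fewer counts (edgeR adjusted p = 0.134). Background could thus give at most part of the WT globins of endothelial-like cells. How much of the difference it gives remains open there and in the other classes.

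An unnamed cluster of 53 cells entered no class comparison, though its cells are part of the sums over all called cells. It had the cilium genes tuba7l, dnali1 and tekt1 among its leading genes, and 26 of its cells came from WT replicate 3. Male germ cells from a neighbouring testis were tested by listed germ cell genes, and 7 genes, among them piwil1 (33.96% of cells), sycp3 (30.2%) and hormad1 (39.62%), were held by at least 20% of its cells at 10 or more times the share of other cells. Those values are consistent with spermatogenic cells in WT replicate 3, where 11 of the 17 listed genes reached 20% of the cells and 20 of 26 cells carried ddx4, piwil1, sycp3 or hormad1, as did 3 of 14 cells of WT replicate 2 and 1 of 9 mpi+/- cells. Ciliated cholangiocytes were excluded for the cells of WT replicate 3 as a whole, since those 11 genes, like the 7 of the whole cluster, lay under 2% in cholangiocyte-like cells, and the epithelial genes epcam, anxa4 and sox9b had a median of 0 against 174 per 10000 UMIs. In the 27 cells of the other libraries 0 of the 17 genes reached 20% and that median was 141, so ciliated cholangiocytes remain open there beside single germ cells.

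The largest stellate/mesenchymal-like cluster, of 393 cells, carried stellate and endothelial markers together. Multiplets of an endothelial and a stellate cell would add no stellate level of their own, and 0% of its 39 detected stellate markers exceeded 1.5 times the highest level of the other stellate and endothelial clusters, which is consistent with multiplets. Its median of 10885 UMIs lay above the 7386 of all called cells. Predicted doublets made up 2.48% of its cells against 3.30% of all, a ratio of 0.752. Simulated doublets were random pairs of cells that were mostly hepatocyte-like, so few joined an endothelial and a stellate cell. The number predicted per library was also set in advance, so this ratio cannot exclude such doublets. The other stellate/mesenchymal-like clusters held 107 and 54 cells, and the largest cluster outnumbered each of them in every library. Random pairing of a stellate with an endothelial cell would give fewer such pairs than single stellate cells. These counts argue against random doublets as the source of the whole cluster. Cells that stayed attached through dissociation remain open.

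Pancreatic endocrine-like cells, a class without a gene test of its own, numbered 244 in mpi+/- replicate 2, or 5.36% of that library. They are part of the sums over all called cells. The Leydig cell gene insl3 had 2287 of its 2291 UMIs in WT replicate 3.

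With 10 splits of the 6 libraries into 3 and 3, a share under 0.05 cannot be reached. The number of splits with as many genes as the real one was 10 in hepatocyte-like cells (real 0, highest other 7), 3 in stellate/mesenchymal-like (1 and 3), 1 in endothelial-like (7 and 0), 10 in macrophage-like (0 and 0), 10 in cholangiocyte-like (0 and 1), 4 in T/NK-like (1 and 8) and 10 in all called cells (0 and 3). For lists, splits with as many numbered 1 in hepatocyte-like cells (real 9, highest other 5), 6 in stellate/mesenchymal-like (4 and 6), 5 in endothelial-like (3 and 6), 8 in macrophage-like (1 and 5), 8 in cholangiocyte-like (4 and 7), 7 in T/NK-like (2 and 3) and 6 in all called cells (10 and 19). The split of WT replicates 1 and 2 with mpi+/- replicate 3, which follows the background groups, gave the 19 lists of all called cells and the 8 genes of T/NK-like cells. With background as a factor, genotype gave 14 lists in all called cells and 1 gene in T/NK-like cells.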

How the results depend on the processing

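Calls depended on single libraries and on the model, and the cause was not tested. Of the alternatives for counts and shares, 305 were labelled alike, 85 moved and 14 reversed in sign. A count was labelled as moved when it changed by over 1.5 times or ended a count of 0. A share was labelled alike when it kept its sign and stayed without a call, however far its value moved. Of the alternatives for single genes and lists, 605 were alike, 211 weaker, 33 stronger and 6 reversed.

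Within the high-background libraries the share differences were −0.0883 points for hepatocyte-like, 0.177 for stellate/mesenchymal-like, 0.427 for thrombocyte-like and −0.0280 for pancreatic endocrine-like cells, and T/NK-like cells stood at −1.98 within the low-background libraries. Without hepatocyte-like and erythroid-like cells in the total, the stellate/mesenchymal-like difference was 1.45. Without 1 library the differences ran from −1.39 to 1.96 for endothelial-like, −1.69 to 1.47 for T/NK-like, −0.422 to 0.0113 for thrombocyte-like and −0.0734 to 2.60 for pancreatic endocrine-like cells.

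Gene counts below follow the order hepatocyte-like, stellate/mesenchymal-like, endothelial-like, macrophage-like, cholangiocyte-like, T/NK-like and all called cells. DESeq2 gave 366, 5, 16, 3, 4, 4 and 210 genes, and genes with any count gave 62, 28, 39, 14, 16, 14 and 5. Background-subtracted sums gave 3 genes in stellate/mesenchymal-like, 0 in endothelial-like and 0 in T/NK-like cells. Background as a factor gave 2 in stellate/mesenchymal-like and 2 in endothelial-like cells. The vitellogenin covariate gave 2 in stellate/mesenchymal-like, 1 in endothelial-like, 2 in macrophage-like and 0 in T/NK-like cells. Keeping predicted doublets gave 3 in hepatocyte-like cells, 2 times the resolution gave 2 in stellate/mesenchymal-like cells, and the sum over all barcodes gave 3 in all called cells. Without 1 library, counts ran from 0 to 3, 1 to 5, 2 to 8, 0 (macrophage-like), 0 to 1, 0 to 4 and 0 (all called cells).

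Lists with an estimated correlation numbered 0 in all 7. Fry gave 1 in hepatocyte-like cells and 0 in stellate/mesenchymal-like, endothelial-like, macrophage-like, cholangiocyte-like and all called cells. Background as a factor gave 1 in endothelial-like cells, the vitellogenin covariate gave 2 in stellate/mesenchymal-like, 2 in macrophage-like and 4 in T/NK-like cells, and background-subtracted sums gave 2 in cholangiocyte-like cells. Without 1 library, list counts ran from 3 to 6, 2 to 6, 1 to 5, 1 to 3, 1 to 5, 2 to 4 and 7 to 16. With the vitellogenin covariate, the camera direction reversed for interferon in hepatocyte-like cells (median −0.0017), and medians changed sign for acute phase in stellate/mesenchymal-like (0.19), lipoprotein in endothelial-like (0.13), and xenobiotic (−0.0913) and interferon genes (0.18) in all called cells. Lipoprotein genes in endothelial-like cells ran from −0.53 to −0.13 without 1 library. In WT, genes higher ran from 96 to 170 in endothelial-like, 103 to 191 in cholangiocyte-like and 48 to 148 in erythroid-like cells without 1 library, and background-subtracted sums gave 79 in erythroid-like cells.

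Whether equal numbers in the titles mark pairs could not be decided, and the libraries were treated as unpaired. Correlations of same-number pairs were 0.179, 0.204 and −0.376, within the range of different-number pairs, −0.524 to 0.382. With the replicate block, genes numbered 4 in stellate/mesenchymal-like, 6 in endothelial-like, 1 in macrophage-like, 2 in cholangiocyte-like and 0 in T/NK-like cells, lists numbered 5 in hepatocyte-like and 1 in endothelial-like cells, and the T/NK-like share stood at a log2 of −0.32. Of the 7 endothelial-like calls, 4 were among those 6, and mt-rnr1, mb and icn had edgeR adjusted p of 0.119, 0.121 and 0.119.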

Other observations

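The WT classes also differed in lists not described so far. Hepatocyte-like cells of WT livers had higher lipogenesis genes, with 8 of 9 higher at a median 4.3 log2 units above all tested genes (camera adjusted p = 0.00495, and 0.223 with an estimated correlation). The elongase gene elovl2 and the desaturase gene fads2 stood at log2 5.44 (SE 0.37) and 5.73 (SE 0.40). Xenobiotic metabolism genes were higher in 19 of 23 cases, by a median of 4.1 (camera adjusted p = 9.71e-05, and 0.223 with an estimated correlation). Heat shock and inflammatory genes were lower there, at medians of −3.32 and −3.37 (camera adjusted p = 8.93e-07 and 0.0119, and 0.223 each with an estimated correlation). T/NK-like cells of WT livers had higher circadian clock genes in 10 of 16 cases (camera adjusted p = 0.00266, and 0.426 with an estimated correlation), with the clock output gene tefa at log2 2.38 (SE 0.24).

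In WT cholangiocyte-like cells 20 of 26 immediate early genes were higher, at a median 1.55 above the class median (camera adjusted p = 0.00194, and 0.795 with an estimated correlation), with fosl1a at log2 3.17 (SE 0.30) and atf3 at 2.92 (SE 0.31). The same list was higher in 17 of 26 genes of endothelial-like cells, at 1.64 (camera adjusted p = 1.66e-04, and 0.561 with an estimated correlation). In hepatocyte-like cells it stood at −2.28. Pancreatic acinar-like cells formed 0.0321% ± 0.00756 of WT and 0.222% ± 0.286 of mpi+/- cells (SD, n = 3; exact permutation p = 0.4, adjusted 0.686), and 25 of them came from mpi+/- replicate 2.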
